A study of Homo sapiens with 9 samples.

How the data were processed

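The series holds 9 expression arrays of LNCaP prostate cancer cells. The titles place 2 arrays in a vehicle group, 2 in a bic group and 1 at each of 5 doses of R from 10 to 810 pM, and the replicate numbers 1 and 2 of vehicle and bic come from the same titles. The deposited table gives 1 linear intensity per probe set and array for 22283 probe sets. What the authors did to make these deposited intensity values, including the program that summarised the probes, is not given in the sources used here. The deposited values show that each array had been scaled, since the 2% trimmed mean was 2501 in every array. The array design comes from the comment line of the probe table.

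Genes were named from the platform annotation of the probe sets. Of the 22215 probe sets other than controls, 19065 have 1 gene symbol, 1043 have several and 2107 have none or are not listed, and no gene was named from a probe set with several. Symbols were checked through Entrez identifiers against a RefSeq gene table of the GRCh38.p14 assembly, which changed 0 symbols, and 1 list gene was looked up under another symbol. No coordinates were used. Genes of the lists that the annotation does not name were not analysed here, including 5 of the 22 core androgen-induced genes, and 5 more lay under the filter.

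The 68 control probe sets were left out of the tests. Each array was scaled by 1 factor to the same median, values under the 20th percentile of all pooled values (an intensity of 116, or 6.85 on the log2 scale) were set to that floor, and log2 was taken. Probe sets with a mean log2 above the 40th percentile of all pooled values (8.70) were tested, 13054 in all, which cover 7866 genes. The array number limits the precision, and a change against values at the floor is a lower bound. Where a gene had several probe sets, the one with the highest mean over all 9 arrays stood for it.

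The test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with a variance trend, on all 9 arrays, so that all groups shared 1 estimate of the spread with 5 residual degrees of freedom. The design had a vehicle mean, a bic mean, an R mean and an R slope on the log of dose, centred at 90 pM in 3-fold steps. The 4 comparisons were bic against vehicle, R against vehicle (the mean over 5 doses), the R dose slope and bic against R. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested in a comparison, with a threshold of 0.05. Errors of changes are standard errors from the fit. The control is vehicle throughout, and per-array values are changes from the mean of the 2 vehicle arrays.

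The 19 gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, and adjusted over the lists of a comparison, with the correlation estimated per list as an alternative. This test sets a list against all other genes tested, so its direction is relative to them and not to 0. No list call in any of the 4 comparisons held with an estimated correlation. That alternative changed more than the correlation, since p rose also where the estimate was below the preset. For polyamine genes in R against vehicle the estimate was -0.01, and the unadjusted camera p went from 0.00991 to 0.0419. The loss of a call is thus no measure of the correlation between genes of a list. The lists hold core androgen-induced, broad androgen response and androgen-repressed genes, cholesterol and fatty acid synthesis, DNA replication and G1/S, mitosis and G2/M, endoplasmic reticulum folding, polyamine synthesis, glycolysis, hypoxia, p53 targets, immediate early genes, interferon-stimulated genes, ribosomal proteins, and markers of neuroendocrine, luminal, basal, stromal and blood cells. For single doses, a list's median was set against 10000 random lists of the same size matched on mean level, as a description of that array.

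The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named were the 10 higher and 10 lower genes with the largest fold among those past the threshold. Where fewer passed, the first by p were given as values, to 5 per direction. In addition came every measured core androgen-induced and androgen-repressed gene and, from each other list, up to 4 members with the smallest p. The test code was run on simulated data built on the 13054 probe sets, with noise drawn independently for each value. It recovered 88.1% of 67 probe sets set to a log2 change of 1 for R against vehicle, 73.1% for bic against R and 91.0% of those set to a slope of 0.5. For smaller changes it recovered less, 26.9%, 23.9% and 10.4% at a log2 change of 0.5 for R against vehicle, bic against R and bic against vehicle, and 56.7% at a slope of 0.25.

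Alternatives were quantile normalization, no scaling, other floors, a pseudocount, other filters, other variance models, array weights, a quadratic dose term, the arrays of each comparison alone, the replicate number as a block, the mean of all probe sets of a gene, dose ranks, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.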

Results

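Transcript levels in LNCaP, an established line of human prostate cancer cells that responds to androgen, were measured on 9 Affymetrix human expression arrays, each with total RNA of 1 sample. All 9 sample titles carry the word Vector. Vehicle-treated cells gave 2 arrays and bic-treated cells 2 arrays, while R was given at 10, 30, 90, 270 and 810 pM with 1 array per dose. The labels spell out neither bic nor R. The gene lists were chosen on the reading that R is a synthetic androgen and bic an antiandrogen, which the labels do not state. Nothing says that arrays of a group came from separate cultures, so the spread between them may be technical. The p-values rest on the spread within the vehicle and bic pairs and on departures of the R arrays from a straight line in log dose. A curved dose response thus adds to the error. The number of arrays limits the precision, and no R dose has a replicate. The deposited array medians ran from 676 to 799 intensity units.

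Signs of RNA quality differed between the arrays. The median of 12 ribosomal RNA control probe sets lay 1.71 (log2) above the vehicle mean in bic replicate 1 and 1.39 above it in bic replicate 2, while the vehicle arrays themselves lay at -0.58 and 0.58. In the R arrays it was 0.34, -0.01, 0.48, 1.03 and 0.74 from 10 to 810 pM. The ratio of 3-prime to 5-prime signal of ACTB, which encodes beta-actin, was 1.55 and 1.73 in vehicle, 1.99 and 1.45 in bic replicates 1 and 2, and between 1.31 and 1.66 in the R arrays. For GAPDH this ratio was 0.972 and 1.13 in vehicle, 1.21 and 1.16 in bic replicates 1 and 2, above both vehicle arrays, and between 1.07 and 1.25 in the R arrays. After scaling, the median over all tested genes lay at -0.16 from the vehicle mean in the 10 pM array, against -0.07 to -0.02 in the other R arrays, so that values at 10 pM are best read against that shift.

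The comparison of R with vehicle asks which transcripts moved in R-treated cells on average over the 5 doses. Several genes long known as androgen-induced rose. FKBP5, a co-chaperone of steroid receptors, rose by 3.55 ± 0.69 (log2 change ± SE, 5 R arrays against 2 vehicle arrays), with 1 of the 2 vehicle arrays at the intensity floor. KLK2, a prostate kallikrein, rose by 2.38 ± 0.26, or 5.20-fold, and KLK3, which encodes prostate-specific antigen, rose by 2.26 ± 0.39, or 4.78-fold. The probe sets of these 2 closely similar kallikreins can share signal. UGT2B17 and UGT2B15, which conjugate androgens with glucuronic acid, had log2 changes of -2.52 ± 0.39 and -1.88 ± 0.25, and being near-identical they cannot be taken as independent.

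Of the 12 core androgen-induced genes measured, 7 rose, and 11 passed when adjusted over the list alone. Besides FKBP5, KLK2 and KLK3 these were SPDEF, a prostate epithelial transcription factor (0.99 ± 0.11), NDRG1 (0.93 ± 0.19), the membrane protease TMPRSS2 (0.87 ± 0.13) and the zinc finger factor ZBTB16 (0.75 ± 0.17). ELL2 at 1.32 ± 0.49 with 1 R array at the floor, CAMKK2 at 0.58 ± 0.21, ABCC4 at 0.44 ± 0.13, TPD52 at 0.40 ± 0.10 and SGK1 at -0.33 ± 0.24 did not pass over all probe sets. The list's median change was 0.90 (camera adjusted p = 4.1e-17, and adjusted p = 0.0696 with an estimated correlation). In the broad list of 79 androgen response genes, 15 rose and 27 passed when adjusted over the list alone. UAP1, an enzyme of UDP-N-acetylglucosamine synthesis, rose by 1.09 ± 0.16 and the acyl-CoA binding protein DBI by 0.88 ± 0.10. The broad list's median was 0.24 (adjusted p = 4.08e-21, and adjusted p = 0.0696 with an estimated correlation), and 17 of its 100 genes are also in the core list of 22.

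Some cell cycle genes rose as well. All 37 measured genes of mitosis and G2/M had positive changes with a median of 0.85, and 11 of them passed over all probe sets and 33 when adjusted over the list alone. NUSAP1, a spindle protein, rose by 1.05 ± 0.17, the mitotic transcription factor FOXM1 by 1.11 ± 0.23 and the securin gene PTTG1 by 0.98 ± 0.16. Of 36 DNA replication genes, 4 rose (CDC45 by 1.61 ± 0.34, RRM2 by 1.29 ± 0.29, GINS2 by 0.73 ± 0.16 and PCNA by 0.68 ± 0.16), 23 passed when adjusted over the list alone, and the median was 0.55. The camera adjusted p was 9.35e-34 for mitosis and 9.72e-21 for replication, and with an estimated correlation the adjusted p was 0.116 for both. Outside the lists, the kinesin KIFC1 (2.06 ± 0.33), the chromosomal passenger gene CDCA8 (1.64 ± 0.28), the chromatin ATPase ATAD2 (1.57 ± 0.22), the helicase-nuclease DNA2 (1.34 ± 0.30), the peroxisomal oxidase ACOX3 (1.54 ± 0.34) and the potassium channel KCNMA1 (1.35 ± 0.20) were among the 10 genes that rose by most.

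Some androgen-repressed genes fell. Of 13 measured, 6 were lower over all probe sets and 10 when adjusted over the list alone, with a list median of -0.89 (adjusted p = 6.15e-09, and adjusted p = 0.0696 with an estimated correlation). Besides the UGT2B genes these were BCHE, which encodes butyrylcholinesterase (-1.10 ± 0.15), the chemokine receptor ACKR3 (-1.06 ± 0.17), the kappa opioid receptor OPRK1 (-0.89 ± 0.13) and CAMK2N1 (-0.58 ± 0.11). NTS at -0.97 ± 0.27, AKR1C3 at -0.96 ± 0.39, SERPINI1 at -0.87 ± 0.35, DDC at -0.40 ± 0.13, PEG3 at -0.27 ± 0.13, FOLH1 at 0.02 ± 0.13 and MET at 0.23 ± 0.27 did not pass. The other genes with the largest falls were CHN1, a Rac-regulating chimaerin (-2.23 ± 0.39), LPCAT4 (-1.78 ± 0.22), the myosin kinase MYLK (-1.58 ± 0.27), the tetraspanin TSPAN8 (-1.45 ± 0.23), the inhibitor of differentiation ID3 (-1.45 ± 0.28), TUBA1A (-1.44 ± 0.17), AMIGO2 (-1.40 ± 0.29) and the interleukin-1 antagonist IL1RN (-1.34 ± 0.21).

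Among 21 genes of cholesterol and fatty acid synthesis 3 rose, over all probe sets and over the list alone. INSIG1, a sterol-sensing regulator, rose by 1.001 ± 0.15, FASN, the fatty acid synthase, by 0.68 ± 0.12 and ACACA, the acetyl-CoA carboxylase, by 0.76 ± 0.11, with the 1 other probe set of ACACA on the opposite side of 0. The list median was 0.20 (adjusted p = 1.99e-06, and adjusted p = 0.0696 with an estimated correlation). In the hypoxia list of 18 genes NDRG1 was higher while ADM (-1.01 ± 0.18), DDIT4 (-0.62 ± 0.13) and INSIG2 (-1.27 ± 0.29) were lower.

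In all, 280 of 13054 probe sets passed the limma test at an adjusted p of 0.05, 126 higher (76 genes) and 154 lower (106 genes), and the median change over all probe sets was -0.07. The higher share was 45.0% here, against 57.5% after quantile normalization and 59.0% with the values as deposited. The count was 0 without vehicle replicate 1, 21 without vehicle replicate 2, 522 and 520 without bic replicate 1 and 2, and 146 and 125 without the 90 and 270 pM arrays. It was 19 without the filter on dim probe sets, 20 without the variance trend, 92 with the floor at the 40th percentile, 462 with array weights and 520 from the 7 arrays of this comparison alone.

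**Figure D1:**
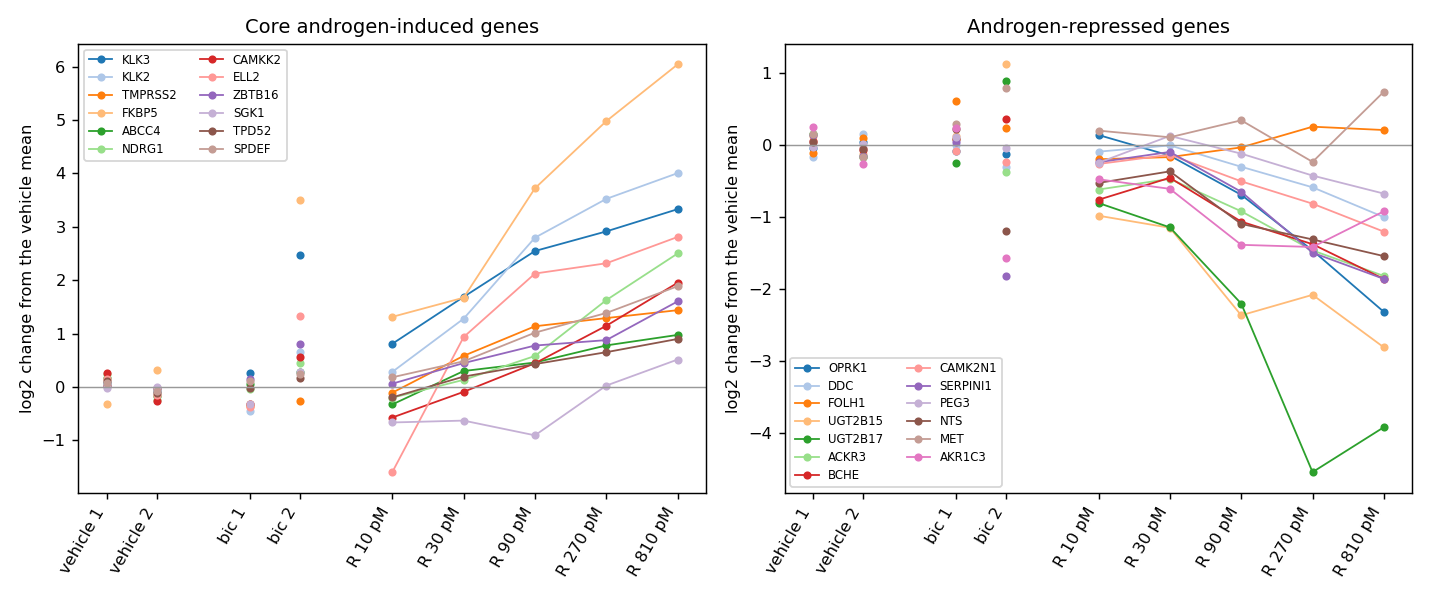
Log2 change from the mean of the 2 vehicle arrays (vertical axis) of each measured core androgen-induced gene (left, 12 genes) and androgen-repressed gene (right, 13 genes) in each array (horizontal axis), with lines joining the 5 R doses and 1 point per array. All 12 core genes were highest at 810 pM among the R doses, and FKBP5 stood at 3.51 in bic replicate 2 and at -0.32 in bic replicate 1.

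The slope over the 5 R doses, in log2 change per 3-fold step from 10 to 810 pM, asks which transcripts followed the dose. The slope itself is computed from the R arrays alone, while all 9 arrays enter the estimate of its error. FKBP5 had the steepest rise at 1.28 ± 0.26 per step, followed by the condensin subunit NCAPD3 at 1.195 ± 0.17, the elongation factor ELL2 at 1.02 ± 0.19 (1 R array at the floor) and KLK2 at 0.97 ± 0.10. The steepest falls were those of CHN1 at -1.03 ± 0.15 and UGT2B17 at -0.96 ± 0.15. At 810 pM, KLK2 stood 16.1-fold and KLK3 10.1-fold above the vehicle mean, while UGT2B17 stood 15.1-fold and CHN1 17.3-fold below it, each from 1 array.

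Of the 12 core androgen-induced genes 11 rose with dose, and 12 did when adjusted over the list alone. SPDEF rose by 0.43 ± 0.04 per step, TMPRSS2 by 0.38 ± 0.05, NDRG1 by 0.69 ± 0.07, CAMKK2 by 0.63 ± 0.08, KLK3 by 0.63 ± 0.15, ZBTB16 by 0.35 ± 0.06, ABCC4 by 0.31 ± 0.05 and TPD52 by 0.26 ± 0.04, while SGK1, a kinase, was at 0.30 ± 0.09 (adjusted p = 0.0809). The list's median slope was 0.53 (adjusted p = 8.49e-18, and adjusted p = 0.0577 with an estimated correlation). Its median change from vehicle was -0.15, 0.47, 0.90, 1.34 and 1.92 at the 5 doses in rising order. None of 10000 random lists of 12 genes matched on level had a median as high at 30 pM, and 3293 did at 10 pM. Random lists do not carry the correlation between genes of a list, so such ranks do not show a response to R. Untreated arrays gave extreme ranks too, since 0 of 10000 lists were as low as the ribosomal proteins in vehicle replicate 1. In the broad androgen response list 40 of 79 genes rose, 53 when adjusted over the list alone, with a median slope of 0.21 (adjusted p = 4.5e-27, and adjusted p = 0.0528 with an estimated correlation). Of the androgen-repressed genes 7 of 13 fell, 10 when adjusted over the list alone (which also gave 1 as higher), namely UGT2B17, given above, OPRK1 at -0.62 ± 0.05, UGT2B15 at -0.46 ± 0.10, ACKR3 at -0.34 ± 0.06, BCHE at -0.31 ± 0.06, CAMK2N1 at -0.26 ± 0.04 and DDC, the aromatic amino acid decarboxylase, at -0.24 ± 0.05. Their median slope was -0.30 (adjusted p = 9.97e-11, and adjusted p = 0.0577 with an estimated correlation).

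Some mitosis and replication genes rose with dose, and the list medians were not highest at the top dose. Of the 37 mitosis genes 13 rose, 33 when adjusted over the list alone, with a median slope of 0.30 (adjusted p = 4.2e-18, and adjusted p = 0.19 with an estimated correlation). HMMR rose by 0.59 ± 0.09 per step, the spindle checkpoint gene MAD2L1 by 0.51 ± 0.08 and the kinase gene MELK by 0.45 ± 0.09. The list's median change from vehicle was -0.07, 0.58, 1.27, 1.36 and 1.10 in rising dose order, and 12, 20 and 5 of its genes were highest at 90, 270 and 810 pM. The ribosomal RNA controls lay at 1.03 and 0.74 in the 270 and 810 pM arrays. Of 36 replication genes 7 rose, 19 when adjusted over the list alone, among them MCM10 (0.45 ± 0.09), GINS2 (0.35 ± 0.06) and RFC3 (0.31 ± 0.06), with a median slope of 0.20 (adjusted p = 1.12e-10, and adjusted p = 0.19 with an estimated correlation).

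Some genes of lipid synthesis, the endoplasmic reticulum and polyamine synthesis rose with dose. Of 21 lipid synthesis genes 9 rose, 14 when adjusted over the list alone, among them INSIG1 (0.49 ± 0.06), FASN (0.36 ± 0.04) and ACACA (0.26 ± 0.04), with a list median of 0.17 (adjusted p = 1.21e-10, and adjusted p = 0.0528 with an estimated correlation). Of 33 endoplasmic reticulum genes 7 rose, 10 over the list alone, including the translocon subunit SEC61B (0.23 ± 0.04), the signal peptidase subunit SPCS3 (0.27 ± 0.05) and the chaperone HSP90B1 (0.18 ± 0.04), with a median of 0.11 (adjusted p = 3.21e-05, and adjusted p = 0.19 with an estimated correlation). Of 12 polyamine genes SMS, the spermine synthase (0.43 ± 0.04), and ODC1, the ornithine decarboxylase (0.27 ± 0.04), rose, 6 passed over the list alone, and the median was 0.09 (adjusted p = 0.00754, and adjusted p = 0.104 with an estimated correlation). Further genes with steep rises were SOCS2 (0.88 ± 0.10), PAK1IP1 (0.86 ± 0.08), KCNMA1 (0.82 ± 0.08), the centromere gene CENPN (0.78 ± 0.10) and GNMT, a glycine methyltransferase (0.77 ± 0.07). Those with steep falls were MYLK (-0.71 ± 0.10), ST6GALNAC5 (-0.70 ± 0.15), LPCAT4 (-0.67 ± 0.08), AMIGO2 (-0.66 ± 0.11), NUDT11 (-0.66 ± 0.15), CFHR4 (-0.59 ± 0.13, 1 R array at the floor) and the cadherin CDH3 (-0.59 ± 0.11).

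In all, 623 probe sets had a slope past the limma threshold, 425 rising (256 genes) and 198 falling (128 genes). The rising share was 68.2%, against 53% after quantile normalization and 51.8% as deposited. The count was 202, 388 and 173 without the 10, 270 and 810 pM arrays, 63 without the filter, 278 with the floor at the 40th percentile, 310 without the variance trend, 382 with array weights, and 1168 when the dose rank with vehicle as 0 replaced the log dose. Without the 10 pM array the median slope was 0.15 for mitosis and 0.10 for replication, and without the 810 pM array these were 0.48 and 0.31.

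**Figure D2:**
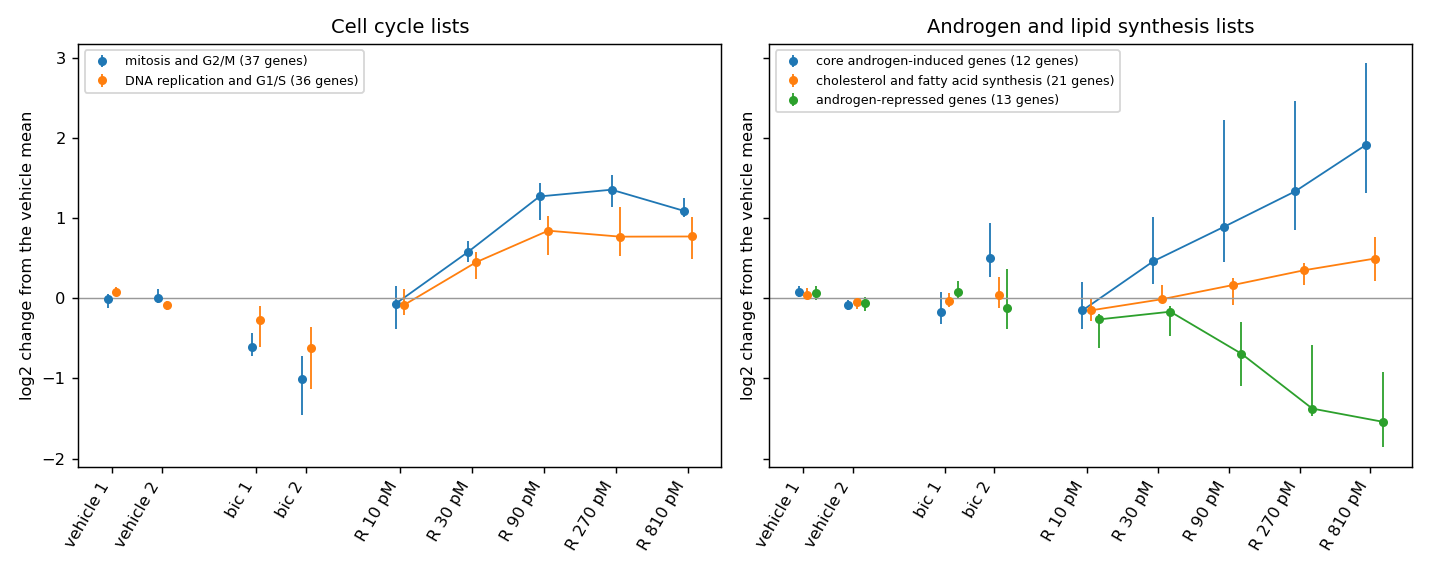
Median log2 change from the vehicle mean (vertical axis, points; bars give the lower and upper quartile over the genes of a list) for 2 cell cycle lists (left) and 3 androgen and lipid lists (right) in each array (horizontal axis), with lines joining the R doses. The mitosis median was -0.60 and -1.01 in the bic arrays and 1.36 at 270 pM, and the core androgen-induced median was highest at 810 pM, at 1.92.

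The comparison of bic with vehicle gave no probe set past the threshold. The genes of cell division nevertheless lay lower as a group. All 37 mitosis genes had negative changes in both bic arrays, with a list median of -0.78 and array medians of -0.60 and -1.01, in arrays whose ribosomal RNA controls lay at 1.71 and 1.39 and whose GAPDH ratios were 1.21 and 1.16. Over all probe sets 0 of them passed, and 24 were lower when adjusted over the list alone. The camera adjusted p was 1.85e-30, and the adjusted p was 0.537 with an estimated correlation. HMMR, a spindle assembly factor, was at -1.33 ± 0.27 (SE, 2 bic arrays against 2 vehicle arrays, adjusted p = 0.343), ASPM at -2.02 ± 0.42 with 1 bic array at the floor, NUSAP1 at -0.95 ± 0.20 and PRC1 at -0.86 ± 0.19. Of 36 replication genes 9 were lower when adjusted over the list alone and 0 over all probe sets, with a median of -0.47 (adjusted p = 5.82e-15, and adjusted p = 0.537 with an estimated correlation) and array medians of -0.27 and -0.63 in bic replicates 1 and 2. MCM10 was at -1.39 ± 0.29 and GINS2 at -0.78 ± 0.19. Outside the lists CDCA8 was at -2.03 ± 0.34 with 1 bic array at the floor (adjusted p = 0.185, the smallest). The lowest p-values among genes with higher levels belonged to DIO3, a deiodinase (0.74 ± 0.14), TNK1 (0.999 ± 0.20), CDC14B (0.94 ± 0.21), ABHD3 (1.13 ± 0.26) and the cystine transporter SLC7A11 (0.74 ± 0.17), which did not pass.

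The core androgen-induced genes differed between the bic arrays by more than they differed between bic and vehicle. Their median was -0.17 in bic replicate 1 and 0.50 in bic replicate 2, and all 12 were higher in replicate 2. KLK3 was at 0.26 and 2.48, FKBP5 at -0.32 (at the floor) and 3.51, ELL2 at -0.37 and 1.33 and KLK2 at -0.45 and 0.65 in replicates 1 and 2, while TMPRSS2 was at -0.35 and -0.25. The fitted changes were 1.37 ± 0.47 for KLK3 and 1.60 ± 0.82 for FKBP5, and for the list the median was 0.18 (adjusted p = 0.034, and adjusted p = 0.67 with an estimated correlation), with 0 of 12 genes passing over all probe sets or over the list alone. Without bic replicate 2 the list median turned to -0.17 (adjusted p = 0.652). The other core genes had fitted changes between -0.30 for TMPRSS2 and 0.49 for ZBTB16. The androgen-repressed genes had a median of -0.10 (adjusted p = 0.953) with 0 of 13 passing, and its sign did not hold, at 0.09 without bic replicate 2 and 0.01 without either vehicle array. Among them SERPINI1, NTS and AKR1C3 were at 0.05, 0.22 and 0.23 in replicate 1 and at -1.82, -1.19 and -1.57 in replicate 2, while UGT2B15 was at 0.13 and 1.12.

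Interferon-stimulated genes had a median of -0.20 (adjusted p = 0.00585, and adjusted p = 0.537 with an estimated correlation), with IFITM3 (-0.71 ± 0.16) and IFITM2 (-0.66 ± 0.16) lower when adjusted over the list alone. Their array medians were -0.04 and -0.43 in bic replicates 1 and 2. Endoplasmic reticulum genes had a median of 0.10 (adjusted p = 0.00728, and adjusted p = 0.634 with an estimated correlation) and the broad androgen response genes one of 0.09 (adjusted p = 0.0111, and adjusted p = 0.634 with an estimated correlation), with 0 members passing in either. Without bic replicate 2 the median was -0.04 for interferon-stimulated genes (adjusted p = 0.484) and 0.03 for the broad androgen response genes (adjusted p = 0.795), and without vehicle replicate 2 it was -0.13 (adjusted p = 0.0957) and 0.02 (adjusted p = 0.14). For endoplasmic reticulum genes it was 0.05 without vehicle replicate 2 (adjusted p = 0.0559) and 0.13 without bic replicate 1 (adjusted p = 0.0504). In the limma test 1058 probe sets had an unadjusted p under 0.05, 455 higher and 603 lower, where 653 would come by chance. The count past the adjusted threshold was 19 without the filter on dim probe sets. In simulated data with independent noise a set log2 change of 1 was recovered for 67.2% of 67 probe sets. Those data also held 66 probe sets set to a change of 2, which eases the adjusted threshold. The share does not carry over to the real comparison, where the smallest adjusted p in limma was 0.185. The number of lists past the threshold, 6 here, was 2 without vehicle replicate 2 and 3 without bic replicate 2.

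The direct test of bic against R set the largest gap in the cell cycle. All 37 mitosis genes passed as lower in bic, with a median of -1.64 (adjusted p = 6.41e-59, and adjusted p = 0.113 with an estimated correlation), and all 37 did when adjusted over the list alone. The ribosomal RNA controls were at 1.71 and 1.39 in the bic arrays and between -0.01 and 1.03 in the R arrays. NUSAP1 was at -1.998 ± 0.17 (log2 change ± SE, 2 bic arrays against 5 R arrays), PBK by -2.20 ± 0.22, HMMR by -2.17 ± 0.23, PRC1 by -1.59 ± 0.16, the survivin gene BIRC5 by -2.30 ± 0.30 and the centrosomal kinase NEK2 by -2.27 ± 0.25. ASPM was at -2.77 ± 0.35 and CDCA8 at -3.68 ± 0.28, each with 1 bic array at the floor. RAD54L, a recombination helicase, was at the floor in both bic arrays and thus at least 7.47-fold lower in bic. Of 36 replication genes 23 were lower, 30 when adjusted over the list alone, with a median of -0.82 (adjusted p = 1.6e-35, and adjusted p = 0.113 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, was at -2.57 ± 0.29, CDC45 at -2.68 ± 0.34, MCM10 at -2.03 ± 0.24, GINS1 at -1.64 ± 0.20 and GINS2 at -1.52 ± 0.16.

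Among the 12 core androgen-induced genes 4 were lower in bic than in R, namely KLK2 (-2.28 ± 0.26), TMPRSS2 (-1.17 ± 0.13), SPDEF (-0.81 ± 0.11) and NDRG1 (-0.73 ± 0.19), and 6 were when adjusted over the list alone. FKBP5 at -1.95 ± 0.69 and KLK3 at -0.89 ± 0.39 did not pass. The list median was -0.77 (adjusted p = 2.08e-09, and adjusted p = 0.133 with an estimated correlation), and it was -0.09 without bic replicate 1 and -0.93 without bic replicate 2. In the broad androgen response list 12 of 79 genes were lower and 1 higher, 17 and 3 when adjusted over the list alone, with a median of -0.17 (adjusted p = 3.78e-10, and adjusted p = 0.133 with an estimated correlation). Of the 13 androgen-repressed genes 6 were higher in bic, 7 when adjusted over the list alone, with a median of 0.42 (adjusted p = 7.33e-07, and adjusted p = 0.12 with an estimated correlation) that became 0.91 without bic replicate 2. UGT2B17 was higher by 2.84 ± 0.39, UGT2B15 by 2.50 ± 0.25, BCHE by 1.33 ± 0.15, ACKR3 by 0.91 ± 0.17, OPRK1 by 0.79 ± 0.13 and CAMK2N1 by 0.42 ± 0.11. Of 21 lipid synthesis genes 4 were lower, FASN, DHCR7, ACACA and ACLY, between -0.56 and -0.45, and 8 were when adjusted over the list alone, with a list median of -0.17 (adjusted p = 2.39e-05, and adjusted p = 0.113 with an estimated correlation).

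Other genes higher in bic than in R included CHN1 (2.72 ± 0.39), the chemokine CXCL8 (1.93 ± 0.47), the vasodilator peptide gene ADM (1.73 ± 0.18), the angiopoietin ANGPT2 (1.497 ± 0.25), AOC1 (1.44 ± 0.22), ZBBX (1.43 ± 0.36), ID3 (1.41 ± 0.28) and GEM (1.39 ± 0.24). NMU, which encodes a neuropeptide, was lower at -2.60 ± 0.37 with 1 bic array at the floor. In all, 704 probe sets passed the limma test, 378 higher in bic (262 genes) and 326 lower (213 genes), and the median change over all probe sets was 0.07. The higher share was 53.7%, against 43.1% after quantile normalization and 40.5% as deposited. The count was 333 without bic replicate 2, 440 and 452 without the 90 and 270 pM arrays, 84 without the filter, 434 with the floor at the 40th percentile, 388 without the variance trend and 444 with a quadratic dose term.

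**Figure D3:**
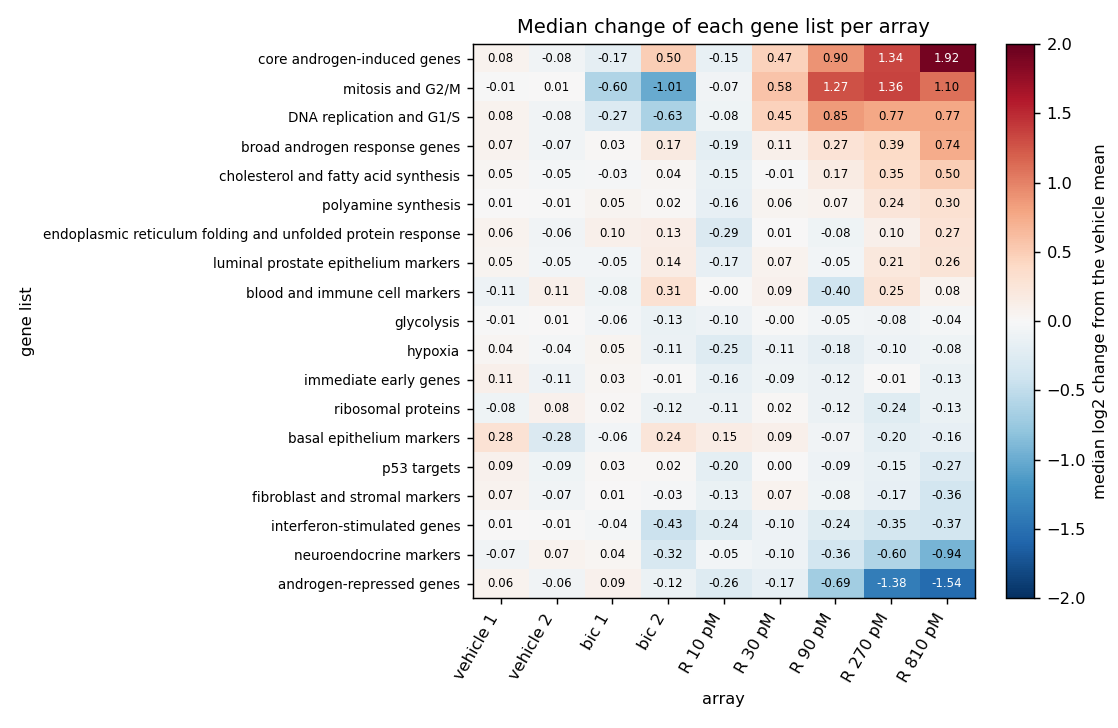
Median log2 change from the vehicle mean (colour and printed value) of each of the 19 gene lists (vertical axis) in each of the 9 arrays (horizontal axis), ordered by the value at 810 pM. The core androgen-induced list stood at 1.92 and the androgen-repressed list at -1.54 at 810 pM, and the mitosis list at -1.01 in bic replicate 2.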

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

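The tests of explanations in this part were chosen only after the result was seen, while the gene and list tests they are set beside were planned. The ribosomal RNA control probe sets, which no comparison uses, gave a median signal above both vehicle arrays in 4 arrays, at 1.71 (log2, from the vehicle mean) in bic replicate 1, 1.39 in bic replicate 2, 1.03 at 270 pM of R and 0.74 at 810 pM.

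Mitosis genes were lower in both bic arrays than in vehicle, beside these ribosomal RNA values. The higher of the 2 bic array medians was at most -0.59 under 3 scalings. The scale factors of the vehicle and bic arrays lay between -0.008 and 0.094 (log2), so leaving them out could move the medians little. The choice among these scalings thus did not make the difference, while the scaling of the deposited values was not tested. If carry-over of ribosomal RNA lowered the mitosis median in proportion to its log2 level, vehicle replicate 2 would lie at -0.58 from vehicle replicate 1. Their ribosomal RNA gap was 1.16, and the observed difference in the mitosis median was 0.0189 with a lower quartile of -0.10. The proportion was assumed, and the ribosomal RNA values of the bic arrays lay above those of both vehicle arrays. RNA degradation cannot be told apart, since the 3-prime to 5-prime ratio of GAPDH was above both vehicle arrays in both bic arrays (1.21 and 1.16 against 0.972 and 1.13), while that of ACTB was above them in bic replicate 1 but below them in bic replicate 2 (1.45). An effect of bic stays open as a hypothesis, as do differences between cultures that the labels do not record, with 0 genes past the threshold over all probe sets and an adjusted p of 0.537 with an estimated correlation.

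The core androgen-induced genes were higher in bic replicate 2 than in bic replicate 1, with all 12 genes in that direction. The median difference was at least 0.59 under 3 scalings. The scale factors of bic replicates 1 and 2 were 0.039 and 0.045 (log2), so leaving them out could change it little. The choice among these scalings thus did not make the difference, while the scaling of the deposited values was not tested. RNA of an R-treated culture in place of that of replicate 2 is argued against by the mitosis genes. Their median in replicate 2 lay at -0.87 from the R array with the lowest one, with an upper quartile of -0.67. RNA of such a culture mixed in stays open. The 810 pM RNA needed over replicate 1 ran from 2.75% to 65.5% over the core genes with a median of 17.8%. Each of these genes was higher than in replicate 1 both in replicate 2 and at 810 pM. The shares were therefore positive in advance and could not count against mixing. The level of replicate 2 without mixing is also unknown. Activity like that of R in this culture may have contributed, but it cannot be told apart from other differences between 2 single arrays of 1 label. Of 384 slope genes, 65.4% moved from replicate 1 to replicate 2 in the direction of their slope, between the bounds set for and against it. These were 175 of 256 rising genes, a set that holds 11 of the 12 core genes, and 76 of 128 falling genes. Of all 7866 genes, 4172 were higher in replicate 2. The mitosis list, whose median slope was positive, moved the other way, by -0.41 with 32 of 37 genes lower.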

How the results depend on the processing

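None of the alternatives was chosen after a result was seen, except that ASNS and CLDN7 were then added to the fits that leave out an array. The medians of the mitosis, replication and androgen-repressed lists kept their direction in each of the settings tried for R against vehicle, the slope and bic against R, and so did those of the mitosis and replication lists for bic against vehicle. The causes of the changes below were not tested, except that fewer or more arrays or genes entered where the setting says so.

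Probe sets past the threshold for bic against vehicle, 0 in the reported fit, numbered 19 without the filter on dim probe sets and 0 to 265 with 1 array left out. For R against vehicle, 280 became 92 with the floor at the 40th percentile, 19 without the filter (7 of them shared with the 280), 20 without the variance trend, 462 with array weights, 520 with the arrays of the comparison alone, and 0 to 522 with 1 array left out. For the slope, 623 became 278 with that floor, 63 without the filter, 310 without the trend, 382 with array weights, 1168 with dose ranks, and 173 to 930 with 1 array left out. For bic against R, 704 became 434 with that floor, 84 without the filter, 388 without the trend, 444 with a quadratic dose term, and 333 to 912 with 1 array left out. Where a group was left with 1 array, that array was assumed to vary like the other groups.

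With an estimated correlation 0 lists passed in any comparison, against 6, 10, 13 and 6 with the preset one for bic against vehicle, R against vehicle, the slope and bic against R. The loss cannot be put down to correlation alone, since p rose also for lists whose estimate was below the preset. The medians do not depend on the choice of correlation. For bic against vehicle they stayed at 0.18 for the core androgen-induced list (adjusted p = 0.67), -0.47 for replication and -0.78 for mitosis (both 0.537). For R against vehicle they stayed at 0.90 for the core and -0.89 for the repressed list (both 0.0696), 0.55 for replication and 0.85 for mitosis (both 0.116). For the slope they stayed at 0.53 and -0.30 (both 0.0577), 0.20 and 0.30 (both 0.19), and for bic against R at -0.77 (0.133), 0.42 (0.12), -0.82 and -1.64 (both 0.113). With 1 array left out the number of lists ran from 2 to 7, 8 to 11, 12 to 13 and 6 to 9.

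The core list in bic against vehicle lost its call with the filter at the 60th percentile (0.17, adjusted p = 0.0633) and without the variance trend (0.18, adjusted p = 0.0884). It ran from -0.17, reversed, without bic replicate 2 to 0.50 without bic replicate 1, with 0.03 (adjusted p = 0.183) without vehicle replicate 2. Ribosomal proteins reversed for R against vehicle without vehicle replicate 2, where the median was -0.0563 and the test pointed up (adjusted p = 0.737), against -0.181 without vehicle replicate 1, and for the slope under quantile normalization at 0.0145 (adjusted p = 0.0477). SERPINI1 in bic against R, at -0.02, ran from -0.953 without bic replicate 1 to 0.913 without bic replicate 2.

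For the lists other than the core, repressed, replication and mitosis lists, the settings other than leaving out 1 array were counted, the estimated correlation included. In 868 results the list stayed on its side of the threshold, with the same direction where it was called. A further 33 lost the call, 5 gained it and 1 reversed. A change of direction without a call in either fit was not counted as reversed. For named genes these numbers were 4960, 333, 99 and 0.

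Vehicle and bic share the replicate numbers 1 and 2, but same-numbered arrays did not deviate together (correlation of deviations -0.01). With 1 difference per group this cannot show whether they shared a culture or batch, which the labels do not give. With the replicate block the counts were 0, 325, 694 and 743, and the core list median for bic against vehicle stayed at 0.18. The floor held 18.8% to 21.3% of the values of an array. That share follows from setting it at the 20th percentile and does not measure background.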

Other observations

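Of the tests in this part, those on the doses of 810 and 270 pM were chosen only after the result was seen, and ASNS and CLDN7 were named, and fitted with each array left out, after their values were seen. In the endoplasmic reticulum list, TRIB3 (0.73 ± 0.13), CHAC1 (0.996 ± 0.17), ATF3 (0.76 ± 0.14), DDIT3 (1.11 ± 0.20) and the asparagine synthetase gene ASNS (0.61), known as targets of the transcription factor ATF4, were higher in bic than in R. These were the 5 of 33 list members that passed, over all probe sets and when adjusted over the list alone. The list as a whole did not pass, with a median of 0.10 (adjusted p = 0.193). Against vehicle none of these genes passed, with CHAC1 at -0.60 ± 0.17 and DDIT3 at -0.67 ± 0.20 in R and TRIB3 at 0.56 ± 0.15 in bic. VEGFA (0.55 ± 0.12), the p53 target SESN1 (0.61 ± 0.13), VIM, which encodes vimentin (0.72 ± 0.17), and SYT1 (1.11 ± 0.22) were also higher in bic than in R. Without bic replicate 2 none of TRIB3, CHAC1, ATF3, DDIT3, ASNS, VEGFA, SESN1, VIM and SYT1 passed, the smallest adjusted p being 0.0544 for CHAC1, and SYT1 was at 0.58.

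Neuroendocrine markers had a median slope of -0.20 over 6 genes (adjusted p = 0.00175, and adjusted p = 0.104 with an estimated correlation), with ENO2 (-0.29 ± 0.05), which the glycolysis list holds too, and DDC (-0.24 ± 0.05) past the threshold and 3 lower when adjusted over the list alone. DDC and NTS of this list are also in the androgen-repressed list, so the lists are not independent. For R against vehicle their median was -0.45 (adjusted p = 0.0971). Luminal markers had a median slope of 0.11 over 14 genes (adjusted p = 0.00147, and adjusted p = 0.111 with an estimated correlation), and KRT18 (0.24 ± 0.04) and AMACR (0.41 ± 0.08) rose beside KLK2 and KLK3, which the list shares with the core androgen-induced list, while CLDN7 was at -0.14 (adjusted p = 0.0448, and between 0.0602 and 0.246 without any 1 of the vehicle or R arrays), and 7 were higher and 1 lower when adjusted over the list alone. For R against vehicle the luminal median was 0.07 (adjusted p = 0.0217, and adjusted p = 0.246 with an estimated correlation), with KLK2 and KLK3 as the 2 genes past the threshold. Stromal markers had a median slope of -0.08 over 10 genes with 0 past the threshold and 3 lower when adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.111 with an estimated correlation), and interferon-stimulated genes one of -0.03 over 27 genes with HLA-B lower at -0.15 ± 0.03 (adjusted p = 0.0148, and adjusted p = 0.262 with an estimated correlation). For R against vehicle the interferon-stimulated median was -0.28 (adjusted p = 0.0283, and adjusted p = 0.379 with an estimated correlation) and that of polyamine genes 0.10 (adjusted p = 0.0217, and adjusted p = 0.116 with an estimated correlation), with 0 genes past the threshold in either, and 0 and 2 when adjusted over the list alone. The 38 ribosomal protein genes had a median slope of -0.03 (adjusted p = 0.000737, and adjusted p = 0.519 with an estimated correlation), which turned to 0.0145 under quantile normalization, and a median of -0.12 for R against vehicle (adjusted p = 0.0139, and adjusted p = 0.701 with an estimated correlation). Single arrays decided several of these calls and non-calls. For R against vehicle, polyamine (adjusted p = 0.0906) and luminal genes (0.0846) did not pass without vehicle replicate 1, interferon-stimulated genes without vehicle replicate 2 (0.283), interferon-stimulated (0.0621) and luminal genes (0.0509) without the 30 pM array, and ribosomal proteins without vehicle replicate 2 (0.737) or the 270 pM array (0.0836), while neuroendocrine markers passed without vehicle replicate 1 (0.0138) or without bic replicate 1 (0.0211) or 2 (0.0215). For the slope, interferon-stimulated genes did not pass without the 10 pM array (0.113), nor stromal markers without the 810 pM array (0.0661). For bic against vehicle, ribosomal proteins passed without vehicle replicate 1 (2.93e-05), bic replicate 1 (0.00145) or the 30 pM array (0.0387) and luminal markers without bic replicate 1 (0.0251). For bic against R, ribosomal proteins (0.00811) and luminal markers (0.0425) passed without bic replicate 2 and interferon-stimulated genes without bic replicate 1 (0.0467). Glycolysis, hypoxia, p53 target, immediate early, basal and blood cell lists passed in none of the 4 comparisons, with medians from -0.23 to 0.17 and a smallest adjusted p of 0.0751, though hypoxia genes did in bic against R without bic replicate 2 (0.28, adjusted p = 0.0464). The median, the mean and the test differed in sign for blood cell markers in 3 comparisons, for p53 targets and immediate early genes in bic against vehicle, for endoplasmic reticulum and basal genes in R against vehicle, for glycolysis in the slope and for luminal markers in bic against R, none of which passed there. The sign of the test is relative to the other genes, whose median was -0.07 beside the basal genes in R against vehicle and 0.08 beside the luminal markers in bic against R.

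Mitosis genes had a lower median at 810 pM than at 270 pM of R, while all 12 core androgen-induced genes were higher at 810 pM. The difference in the mitosis median was -0.20 at most over 3 scalings, with 29 of 37 genes lower. The scale factors of the 270 and 810 pM arrays were -0.025 and 0.008 (log2), so leaving them out could change it little. The choice among these scalings thus did not make the difference, while the scaling of the deposited values was not tested. With 1 array per dose, variation of single arrays cannot be told apart from a turn of the dose response, since the quadratic dose term of the list had a camera adjusted p of 6.93e-24 but an adjusted p of 0.454 with an estimated correlation, and 0 probe sets passed for that term in limma, with 914 at an unadjusted p under 0.05. A turn of the mitosis response between 270 and 810 pM may be worth a replicated dose series.

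The order of the 5 doses was tested as planned. Of the 60 distinct orders of the R arrays, 1, the real one, gave as many as 623 probe sets with a slope past the threshold. The highest other order, with 270 and 810 pM exchanged, gave 218. A chance order is thus unlikely but not excluded, since 1 of 60 is the smallest share this test can give. With 1 array per dose, it cannot tell dose from other differences that ran in the same order. Across probe sets, the change of bic against vehicle had a Pearson correlation of 0.08 with the R slope (Spearman 0.10), described only, since genes are not independent replicates, and 35 of the 60 orders gave one as large. It was -0.03 for bic replicate 1 and 0.13 for bic replicate 2.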
